A study of Drosophila melanogaster with 4 samples.

How the data were processed

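The series measured H3K79me1, the monomethylated form of a lysine in the globular core of histone H3, by chromatin immunoprecipitation followed by sequencing (ChIP-seq). The material was wild-type Oregon-R embryos of Drosophila melanogaster at 14 to 16 h of development. There were 4 samples: 2 ChIP libraries made with an antibody against H3K79me1 and 2 input libraries of chromatin that was not immunoprecipitated. Each ChIP replicate had 1 list of enriched regions, and 1 further list covered the replicate set. The labels of the inputs name the ChIP list that each input served.

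Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The entries of each list are regions of significant enrichment on FlyBase release 5 of the genome, per the file headers. The program that called the regions, its threshold, its minimum region width and the way the replicates were combined for the replicate-set list are not given in the sources used here. Each region has a start, an end and a score. The score is the authors' own value per region as deposited, on a scale that the file headers do not name. Scores were therefore used to rank, filter or compare regions within 1 list, and the percentile of a region is its rank in its own list. The exception was the planned correlation of the scores of overlapping regions between the 2 replicates, which compares no score levels between lists.

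The lists hold no read counts, so the sequencing depth of the 4 libraries is unknown and no counting error can be given for a region. A deeper library lets a caller find weaker regions, so the number and width of regions in a list depend on depth as well as on the chromatin. The inputs entered only through the authors' calls, and no list of input regions was used here. The labels do not say that the replicates came from separate embryo collections. The SD between the 2 replicates therefore measures only the spread of these samples, which may be technical. The p-values come from shifting, spacing or permuting regions, or from sign flips over arms, and describe these lists rather than the variation between embryo collections.

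Starts and ends were taken as 1-based and inclusive, and 1 end that a list gives in scientific notation was read as the whole number it stands for. The lengths of the sequences came from the file headers. The main comparisons used the 6 main arms 2L, 2R, 3L, 3R, 4 and X. The 8 heterochromatic and unplaced sequences of release 5 were described apart from them. The covered share of an arm is the number of base pairs inside regions divided by the length of the arm, and is given as the mean ± SD of the 2 ChIP replicates. Bases that cannot be mapped uniquely were not removed from these lengths.

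Replicates were compared by the Jaccard index, which is the base pairs covered in both lists divided by the base pairs covered in either. They were also compared by the share of regions that overlap a region of the other replicate by at least 1 bp. Both were tested against 10000 circular shifts of replicate 2 within each arm, one-sided, which keep the widths and the spacing of the regions. Scores were compared across pairs of regions, each replicate 1 region with the replicate 2 region of largest overlap, by Pearson's r and Spearman's rho with 100000 permutations, two-sided. A replicate 2 region could enter several pairs. Shared and unshared regions were compared by the ranks of width and score with 100000 permutations, two-sided. Covered shares were also computed in windows of 100 kb. The replicate-set list was made from the same libraries, so its overlap with the replicates was described and not tested. Shares of regions carry 95% Wilson intervals where given, which cover counting error only and treat regions as independent.

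The tests, the groups and the alternative settings that follow were fixed before the data were examined. These settings were the 50% of regions with the highest scores, regions of at least 1000 bp, regions less than 1000 bp apart joined into 1, an overlap of at least 50% of a region in place of 1 bp, a reciprocal overlap of at least 50% with a single region, all sequences in place of the main arms, random placement in place of shifts, each replicate alone, and the replicate-set list in place of the replicates. Settings added after seeing the data were shifts of 20 to 500 kb only, score ranks with width removed, and replicate-set regions at least as wide as the narrowest replicate region. The individual regions named were chosen by a rule: the 5 widest and the 5 highest-scoring regions of the replicate set that overlap a region in each replicate, and the widest region of each main arm. Windows, unshared regions, stretches without regions and scores by chromosome were not part of the plan, and places named from them or outside the rule were chosen after their values were seen.

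Planned tests on genes (genic features, gene length and 22 gene lists) were not run, because they need gene positions in release 5 and no annotation of that release was used here. The gene table at hand belongs to release 6, and coordinates were not converted between releases. No region was therefore assigned to a gene, exon or intron.

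The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the figures matplotlib 3.10.9. The interval functions were tested on simulated data against a base-by-base count, and 0 of 120 comparisons differed. In 200 simulated pairs of independent lists, 4.5% had a shift p under 0.05. When 40% of the regions were planted in the second list, 99% of the pairs did.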

Results

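The data collected were lists of genomic regions enriched for H3K79me1 over input in wild-type Drosophila embryos at 14 to 16 h, late in embryogenesis, when organs are differentiating. H3K79me1 is placed by the DOT1 family of methyltransferases, whose fly member is grappa, and H3K79 methylation is generally found over the bodies of transcribed genes. The 4 samples formed 2 groups, with 2 ChIP libraries and 2 input libraries. Each ChIP replicate had its own list, called against an input, and a further list covered the replicate set. Depth is unknown, because the lists hold no counts. All positions are in release 5 of the genome. Gene annotation was not used here, so regions are given by chromosome, start and end.

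The first question was how much of the genome carries H3K79me1 and in what form. Enriched regions covered 32.6% ± 1.12 (SD, n = 2) of the 6 main chromosome arms, 31.8% in replicate 1 and 33.4% in replicate 2. The lists come from embryos and do not separate cell types, so this share need not hold for any 1 cell type. There were many separate regions, 5432 in replicate 1 and 5051 in replicate 2, that together spanned 38.3 and 40.2 Mb. Many neighbours lay close together, and joining regions less than 1000 bp apart left 3769 and 3517. The counts and widths of regions therefore depend on where the calls were cut. Most regions were a few kilobases wide, yet most of the covered sequence lay in the wide ones. Over all sequences, the median width was 4203 bp in replicate 1 and 4623 bp in replicate 2, with middle ranges (25th to 75th percentile) of 2185 to 8517 bp and 2333 to 9519 bp. On the main arms, regions of at least 10 kb made up 20.3% of the regions of replicate 1 and 23.7% of those of replicate 2. They held 55.2% and 61.0% of the covered base pairs. Regions of at least 50 kb numbered 35 and 45. The narrowest region was 1301 bp in each replicate, which is the smallest width either list holds.

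The widest region of the replicate set lay on 3R from 4895724 to 5024732 and spanned 129 kb. Replicate 1 regions covered 98.4% of it and replicate 2 regions 99.5%. The next widest lay on 3L from 2754762 to 2871220 (116 kb) and from 22276824 to 22387588 (111 kb), on 3R from 5708150 to 5816848 (109 kb), and on 3L from 22131806 to 22236218 (104 kb). The last of these and the 111-kb region were close neighbours in the proximal part of 3L. Across these 5 regions, coverage ranged from 89.8% to 98.4% in replicate 1 and from 97.7% to 99.5% in replicate 2. Their scores ranged from the 58.9th to the 99.6th percentile of the list, so a wide region was not always a high-scoring one. The widest region of 2R ran from 15416972 to 15518130 (101 kb), that of 2L from 12454806 to 12545568 (90.8 kb) and that of X from 12111078 to 12193872 (82.8 kb). On 4 the widest region was much shorter, from 529232 to 556884 (27.7 kb), but it was the widest of only 74, against at least 931 on each other arm.

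**Figure D1:**
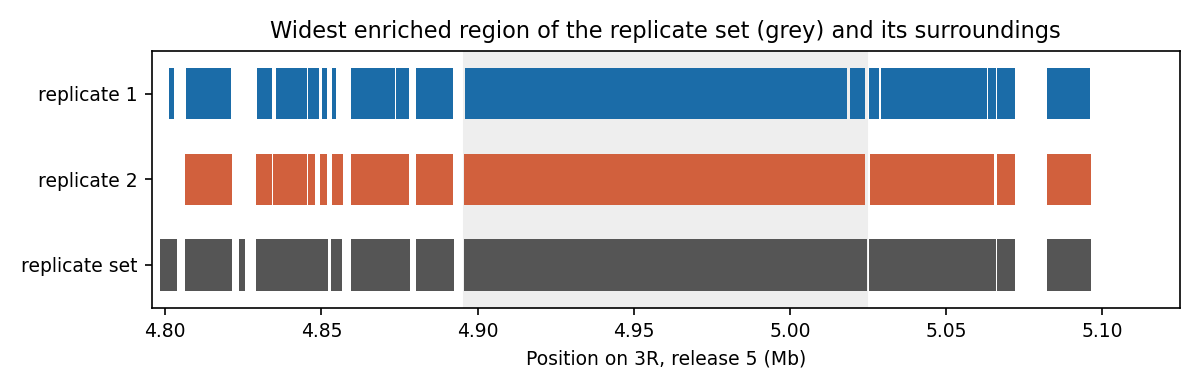
Map of the widest region of the replicate set on 3R (grey band, 4895724 to 5024732) and its surroundings. The x axis gives the position in Mb on release 5, and each bar is 1 enriched region of replicate 1 (blue), replicate 2 (orange) or the replicate set (dark grey); replicate 1 regions cover 98.4% of the band and replicate 2 regions 99.5%.

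The 5 highest-scoring replicate-set regions with a region in each replicate were of very different widths. They lay on 2L from 183496 to 203234 (19.7 kb), on 2R from 17280732 to 17366746 (86.0 kb), on 2L from 3146452 to 3159434 (12.98 kb), on 2L from 10281322 to 10292236 (10.9 kb) and on 3R from 27243060 to 27283312 (40.3 kb). Replicate 1 covered 94.6% to 99.0% of these regions and replicate 2 covered 98.7% to 100%. Across all regions of a list, wider regions had higher scores, with a Spearman rho of 0.801 in replicate 1, 0.804 in replicate 2 and 0.790 in the replicate set. These correlations are across regions, which are not independent replicates.

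The next comparison asked whether the 2 ChIP replicates marked the same sequence. They did so over most of it. Of 42.8 Mb covered in either replicate on the main arms, 35.8 Mb was covered in both, a Jaccard index of 0.837. Of the regions of replicate 1, 4947 of 5432 (91.1%) overlapped a region of replicate 2, and 4398 of 5051 (87.1%) the other way round. Circular shifts gave a Jaccard index of 0.196 ± 0.00744 (SD over 10000 shifts, highest 0.307), and shared regions of 46.2% ± 1.08 and 46.1% ± 1.03. Each of the 3 measures had a one-sided shift p of 0.0001, also after Benjamini-Hochberg adjustment, which is the smallest that 10000 shifts can give. By arm, the Jaccard index was 0.862 on 3R, 0.841 on 2L, 0.838 on 2R, 0.825 on 3L, 0.815 on X and 0.814 on 4.

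The replicates drew their boundaries differently even where they marked the same place. No region had identical coordinates in both. A single region of replicate 2 overlapped at least 2 regions of replicate 1 in 839 cases, with up to 11 in a single region, and the reverse held for 527 regions of replicate 1. When a match required reciprocal overlap of at least 50% with a single region, 3475 pairs remained, 64.0% of the regions of replicate 1 and 68.8% of those of replicate 2. The shifts gave 8.13% ± 0.557 and 8.75% ± 0.599 by that measure.

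Regions found in only 1 replicate were narrow and low in score. The 485 unshared regions of replicate 1 had a median width of 1646 bp, against 4718 bp for shared regions, and a median score percentile of 16.8 against 54.3. The 653 unshared regions of replicate 2 had a median width of 1732 bp against 5562.5 bp, and a median percentile of 13.9 against 56.4. All 4 differences had a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give. Narrow regions also miss a partner more easily by chance. Under 1000 shifts the unshared regions had a median width of 3699 bp ± 60.5 (SD) in replicate 1 and 3945 bp ± 73.0 in replicate 2. Shifts leave most regions unshared, since only 46.2% and 46.1% were shared under them. The shifted medians therefore cannot tell whether the observed unshared regions are narrower than missed partners alone would make them. The widest unshared regions were 7407 and 8054 bp. Unshared regions held 0.889 and 1.31 Mb, less than the parts of shared regions that the other replicate did not cover, 1.64 and 3.13 Mb. These parts include edges as well as gaps between regions of the other replicate.

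**Figure D2:**
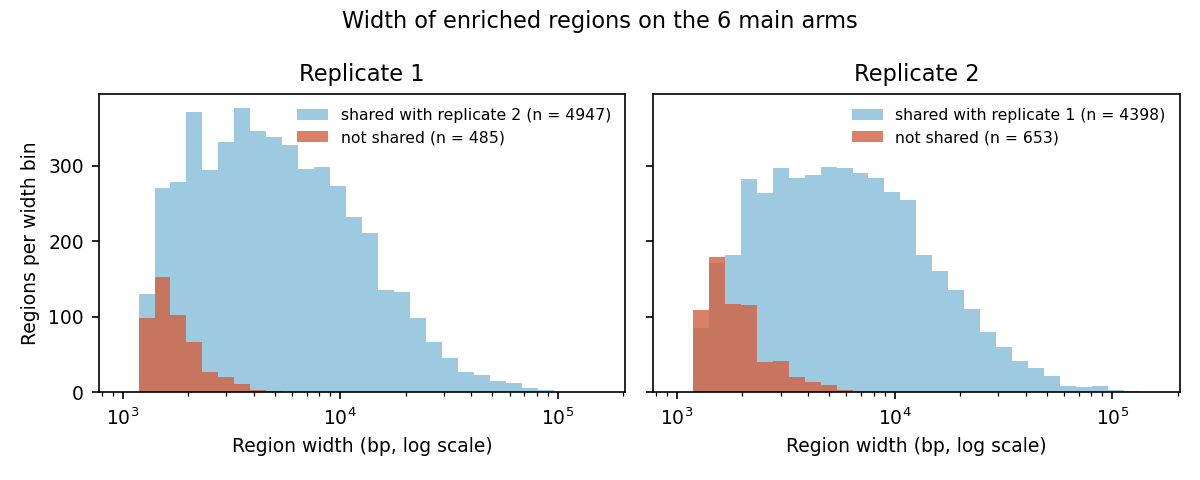
Number of enriched regions per width bin (y axis) against region width in bp on a log scale (x axis) on the 6 main arms, for replicate 1 (left) and replicate 2 (right). Blue bars are regions shared with the other replicate (4947 and 4398) and orange bars those not shared (485 and 653), which crowd at the narrow end with median widths of 1646 and 1732 bp.

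The landscape along the arms was closely alike in both replicates at the scale of 100 kb. Across 1202 full windows, the covered shares correlated with Pearson's r = 0.984 and Spearman's rho = 0.985. Both had a shift p of 0.0001, and the highest r among the shifts was 0.404. Windows are not independent replicates. In 136 windows (11.3%) neither replicate had a region, and 43 windows (3.58%) were at least 80% covered in each replicate. The window with the highest mean share lay on 3R from 4900001 to 5000000, inside the widest region, with 99.7% covered in replicate 1 and 100% in replicate 2. On 2R it lay from 2400001 to 2500000 (93.7% and 94.5%), on X from 19300001 to 19400000 (92.4% and 92.2%), on 3L from 700001 to 800000 (87.4% and 94.1%) and on 2L from 200001 to 300000 (88.9% and 92.5%). On 4 it lay from 500001 to 600000 and reached 51.0% and 57.5%, but 4 had only 13 windows, against at least 211 on each other arm.

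**Figure D3:**
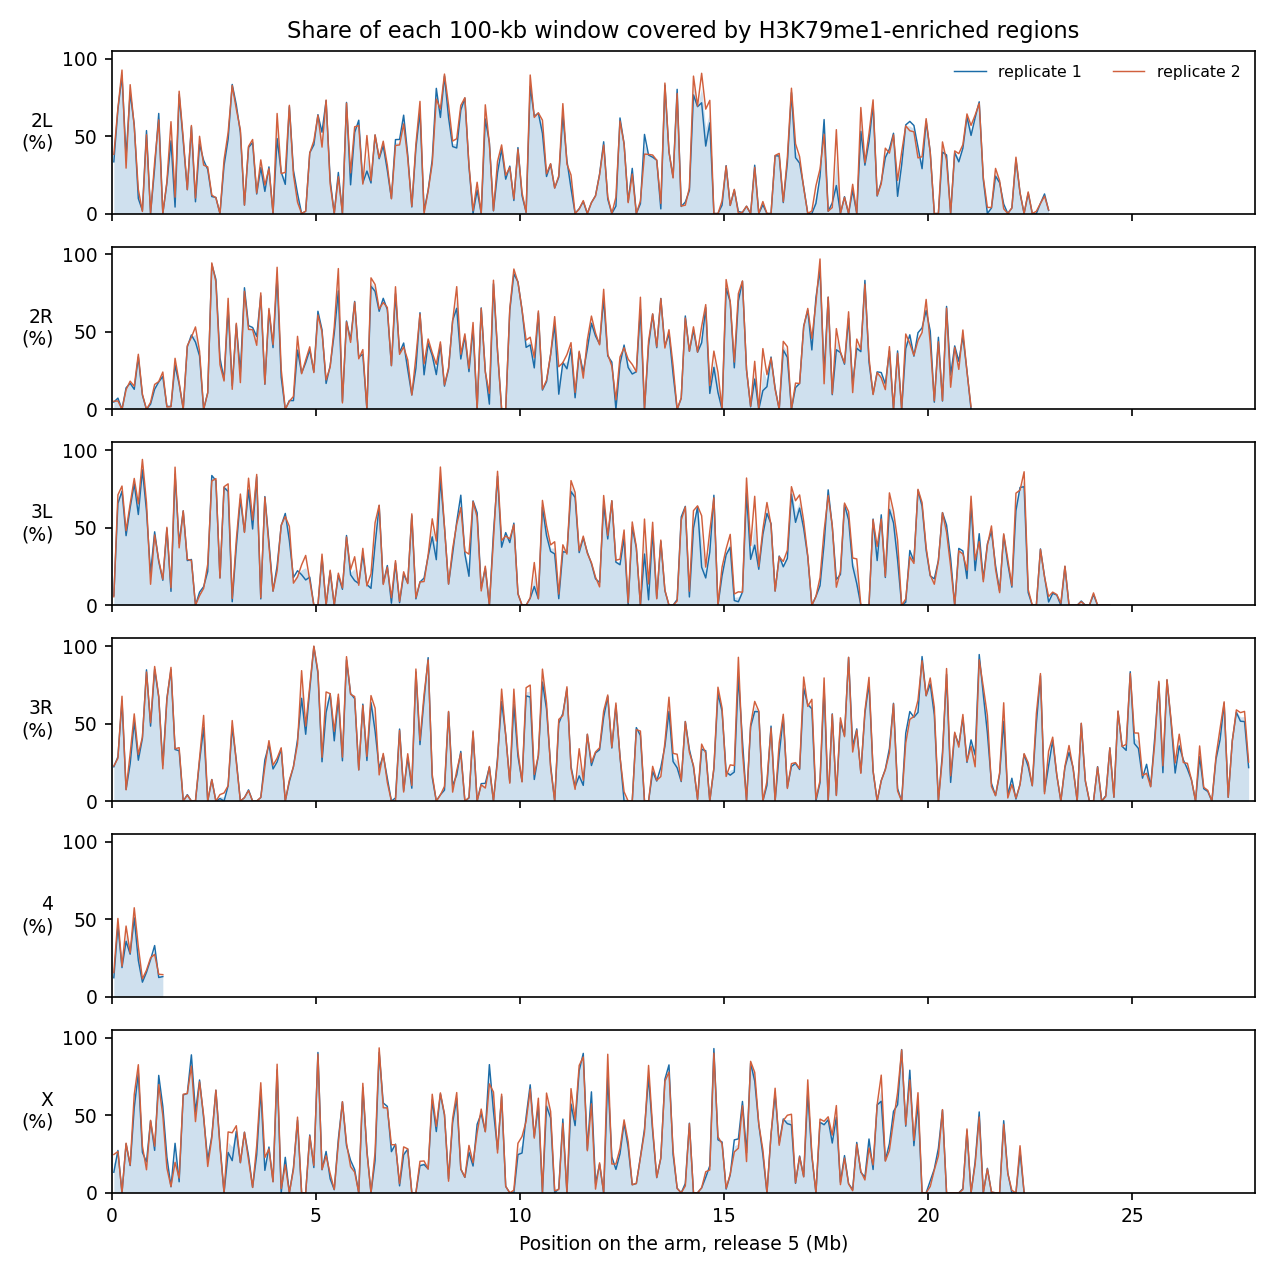
Share of each 100-kb window covered by enriched regions (y axis, percent) along the 6 main arms (x axis, position in Mb on release 5), for replicate 1 (blue line) and replicate 2 (orange line). Shading gives the mean of the 2 replicates. The lines nearly coincide (Pearson's r = 0.984 over 1202 windows), and every arm except 4 has both windows without a region and windows at least 80% covered, with most windows in between (median 29.5% covered). Chromosome 4 has only 13 windows.

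The authors' scores also ranked alike in the 2 replicates. Across the 4947 pairs of overlapping regions, they correlated with Pearson's r = 0.779 and Spearman's rho = 0.776 (two-sided permutation p = 1e-05 for each, the smallest possible, also after Benjamini-Hochberg adjustment over 5 correlations). Among the 3475 pairs with reciprocal overlap of at least 50%, r was 0.875 and rho 0.872. Part of the relation came with width, since wide regions score high in each list. With the rank of width removed from the ranks of both scores, rho was 0.657 (p = 1e-05). These values are across regions, which are not independent replicates. In the 4947 pairs a replicate 2 region could also be the partner of several replicate 1 regions, since 839 overlapped at least 2. The permutations did not account for such repeated partners.

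The list for the replicate set was compared with the replicates to see what it adds to them. It held 5330 regions over all sequences, of which 3625 (68.0%, 95% Wilson interval 66.7% to 69.3%) overlapped a region in each replicate. A further 372 had a region in replicate 1 alone and 528 in replicate 2 alone, and 805 (15.1%) had one in neither. The regions with support in both were wide, with a median of 7669 bp, and held 93.0% of the sequence that the list covers. The regions in neither had a median width of 1245 bp and a median score percentile of 16.5, against 65.7 for those in both. Nearly every replicate region was in the replicate set, 5434 of 5484 (99.1%) for replicate 1 and 5078 of 5107 (99.4%) for replicate 2.

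The replicate set reached 2.67 Mb that neither replicate covered. Of this, 1.55 Mb (58.1%) extended or joined regions of the replicates, and 1.12 Mb lay in regions found in neither. It left out 0.447 Mb that a replicate covered. Its minimum width was also smaller, 1001 bp against 1301 bp, and 535 of its regions were narrower than any replicate region. At the top of its ranking by score, 8 of the 10 highest regions were in neither replicate, 1 (on U from 8055956 to 8056956) was in replicate 2 alone and 1, the 19.7-kb region on 2L, was in both. The list was made from the same libraries, so none of these shares was tested.

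The last comparison asked how H3K79me1 is spread over the chromosomes. Of the 6 main arms, 2R had the highest covered share, 36.1% ± 1.22 (SD, n = 2), and 4, the small chromosome rich in repeats and heterochromatin proteins, had the lowest, 25.3% ± 1.94. Between them lay 3R with 33.0% ± 1.01, 3L with 32.7% ± 1.68, X with 31.1% ± 0.466 and 2L with 30.8% ± 1.13. The same arms were highest and lowest in each replicate and in the replicate set, in which 41.3% of 2R and 29.8% of 4 were covered. Chromosome 4 had 47.3 regions per Mb in both replicates, and the other arms had between 41.8 (2L) and 48.6 (2R) in replicate 1 and between 37.9 (2L) and 46.7 (2R) in replicate 2. Its widest regions were 15.4 and 19.8 kb in the 2 replicates, against at least 73.3 and 81.1 kb on each other arm. Chromosome 4 held only 64 regions in each replicate, against at least 963 and 871 on each other arm. A maximum over fewer regions tends to be smaller. The median widths on 4, 3866 and 4277 bp, compare with 3921.5 to 4445 bp and 4214 to 5148 bp on the other arms.

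The covered share of 4 minus that of the other main arms was -7.37 percentage points ± 0.828 (SD, n = 2), -7.96 in replicate 1 and -6.79 in replicate 2. Between the first and the last region of each arm, 4 was covered to 29.0% ± 2.21, and the other arms to between 30.9% (2L) and 36.1% (2R). The last 113 kb of 4, from 1239344 to 1351857, held no region in either replicate. The covered share of X, the chromosome that is dosage compensated in males, minus that of the autosomal arms was -1.91 points ± 0.801, -1.35 and -2.48 in the 2 replicates. The numbers of reads on X and on the autosomes are unknown, so this difference can reflect the power to call regions as well as the chromatin. This difference is small, and among the 50% of regions with the highest scores it was -0.212 points. That cut is by score, and regions on X had higher median scores at matched width, so it need not treat X and autosomes alike. An exact sign-flip test of 2 libraries cannot give a p below 0.5, so no difference between arms was tested.

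**Figure D4:**
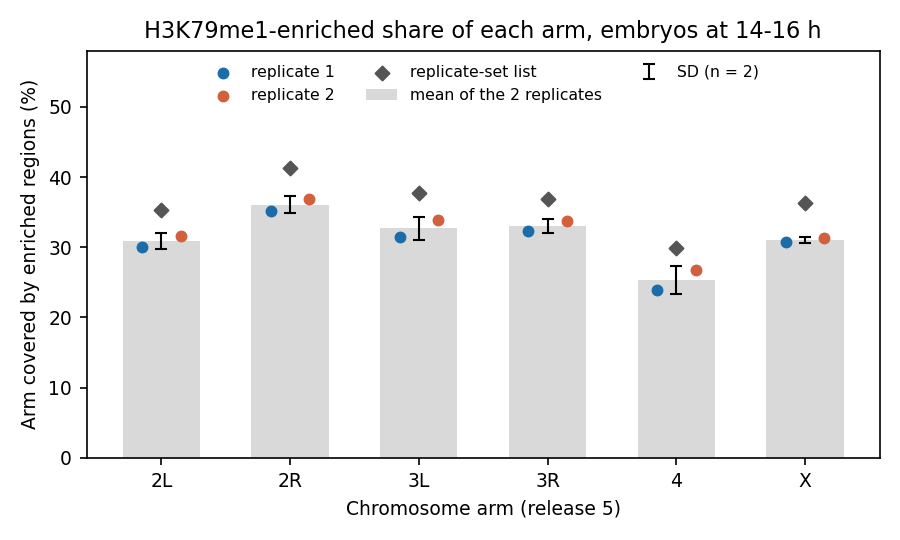
Percent of each main chromosome arm covered by enriched regions (y axis) by arm (x axis). Grey bars are the means of the 2 ChIP replicates with SD (n = 2), circles are replicate 1 (blue) and replicate 2 (orange), and diamonds are the replicate-set list; 2R has the highest mean, 36.1%, and 4 the lowest, 25.3%.

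The 6 sequences that release 5 assigns to heterochromatin, the condensed and repeat-rich DNA around the centromeres and on Y, carried little of the mark. They span 9.28 Mb, of which 1.90% was covered in replicate 1 and 2.07% in replicate 2. The main arms had a covered share 16.4 ± 0.433 (SD, n = 2) times as high. Among the heterochromatic sequences, XHet had 11.5% ± 0.539, 2LHet 3.93% ± 0.274, 2RHet 2.59% ± 0.00538, 3LHet 1.83% ± 0.326 and 3RHet 0.581% ± 0.0358. YHet had no region in either replicate and 1 in the replicate set, from 305632 to 306836. On the 2 unplaced sequences, 0.0373% ± 0.0107 was covered. All of this lay on U, with 0.145% ± 0.0414, while the longer Uextra (29.0 Mb) had no region in any list. Reads from repeats often map to several places, and how the authors treated such reads is not given in the sources used here, so a low share there can also reflect sequence in which regions could not be called.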

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

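Of the tests here, the shift test on these sequences alone and the bootstrap interval of the score percentile were chosen only after the result was seen. The comparison of the replicates in the report used the main arms, with all sequences together as a setting fixed in advance (Jaccard index 0.836), and regions also recurred on the sequences outside the main arms. On the 8 heterochromatic and unplaced sequences, 49 of the 52 regions of replicate 1 overlapped a region of replicate 2, and 43 of the 56 regions of replicate 2 overlapped one of replicate 1. The replicate set held 68 regions there.

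Regions scattered by chance over the whole length of these sequences are argued against by the overlap of the replicates. The Jaccard index was 0.734 against 0.0169 ± 0.0220 (SD over 10000 shifts within each sequence), with a one-sided p of 0.0001, the smallest possible. The shifts used whole sequences, and sequence in which regions cannot be called was neither measured nor removed. The test therefore does not address chance placement within the callable parts alone. Weak regions near the authors' threshold stay open. The median score percentile was 40.3 in replicate 1 and 30.1 in replicate 2, against a bound of 25 set for weak regions, and the 95% bootstrap interval over regions ran from 25.3 to 53.9 in replicate 1, above the bound, and from 20.6 to 42.8 in replicate 2, across it. Recurrent mapping of reads from repeats is also open, since reads were not used here, and no biological explanation was tested because the design has no group that bears on it.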

How the results depend on the processing

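The alternatives named in this paragraph as added were chosen after seeing the data. The filter of at least 1000 bp removed 0 regions and so tests nothing. Leaving aside that filter and the settings without 1 replicate, 6 of the recomputed values of main comparisons without a test moved by more than their spread. Slightly fewer moved by less. The shift p of the replicate overlap was 0.0001 under each alternative, the smallest possible, so it cannot show stability, and the values themselves changed, with the lowest shares, 64.0% and 68.8%, under reciprocal overlap and the lowest Jaccard index, 0.807, among the 50% of regions with the highest scores. The p of the score correlations was likewise at its smallest, 1e-05, and the lowest rho was 0.657, with width removed (added). The share of replicate-set regions found in both replicates was 63.0% when 50% of the region had to be overlapped, a stricter definition. It was 75.6% among regions at least as wide as the narrowest replicate region (added), which leaves out 535 regions. With the 50% of regions of highest score, the covered share of the main arms was 25.5%, by construction lower. X minus autosomes was then -0.212 points and 4 minus the other arms -9.41 points, and the cause was not tested. With the replicate-set list the covered share of the main arms was 37.3%, and the cause was not tested. Leaving out each replicate gave 31.8% to 33.4% for the main arms, -2.48 to -1.35 points for X and -7.96 to -6.79 points for 4, which with 2 replicates cannot lie beyond 1 SD and so shows no stability. Of the other values for single arms and for replicate regions found in the set, 7 moved by less than the spread and 13 by more, 7 of them higher and 6 lower. No paired analysis was possible because the inputs have no list of their own and no test compares the groups that share replicate numbers. The settings listed in advance for genes were not run, as no release 5 annotation was used here. Depth is unknown, so it cannot be said how many of the weak, unshared regions a deeper library would share.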

Other observations

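Of the tests here, those of the spacing of regions, of the highest-scoring replicate-set regions and of the scores on X were chosen only after the result was seen. Long parts of the arms held no H3K79me1 region in either replicate. In 192 stretches of at least 100 kb neither replicate had a region, and these added up to 32.7 Mb, 27.2% of the main arms. The longest lay on X from 20396391 to 20897088 (501 kb), on 3L from 24029812 to 24530329 (501 kb), on 3L from 23336849 to 23708277 (371 kb) and on 3L from 18241183 to 18611709 (371 kb). The replicate-set list had 2, 1, 2 and 3 regions in these 4 stretches, in that order, so they were not empty in every list. Such stretches took up 32.1% of 2L, 30.7% of X, 29.9% of 3R, 24.2% of 3L and 19.2% of 2R. On 4 there was 1, from 1239344 to 1351857, which took up 8.32%. Regions placed at random along each arm gave 9.56 ± 2.83 such stretches (SD over 1000 spacings, highest 19, one-sided permutation p = 0.001, the smallest possible), fewer than observed. The random spacings used the whole arm, and sequence in which regions cannot be called was neither measured nor removed, so it could account for part of the excess. Random spacing also does not keep close neighbours together, and 1677 gaps in replicate 1 and 1541 in replicate 2 were under 1000 bp. Such close spacing alone could leave more long stretches empty. The test therefore shows that regions cluster and says nothing further about the empty stretches.

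At the centromere-proximal end of the arm sequences, coverage was low on 4 of the 5 large arms in both replicates. In the proximal 1 Mb, 1.60% ± 0.0478 (SD, n = 2) of 3L was covered, against 34.0% ± 1.75 of the rest of the arm. The shares were 8.76% ± 0.188 against 31.8% ± 1.18 on 2L, 10.4% ± 0.307 against 37.4% ± 1.27 on 2R and 10.7% ± 0.211 against 32.0% ± 0.478 on X. The exception was 3R, where the proximal 1 Mb had 40.8% ± 1.35 and the rest 32.7% ± 1.00. A lower share at this end of the arm sequence was therefore not found on every arm. The end of a release 5 arm sequence need not lie next to the centromere. Release 5 holds heterochromatic sequences apart from the arms, and 3RHet was covered to 0.581% ± 0.0358. Sequence in which regions cannot be called was neither measured nor removed here. Over the 5 arms the mean difference was -19.1 points ± 15.8 (SD), with an exact two-sided sign-flip p of 0.125, where 0.0625 is the smallest possible.

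The replicate-set list held 805 regions with no counterpart in either replicate. A more permissive threshold in that list is a candidate explanation, since their median score percentile was 16.5, under the bound of 25 set for weak regions. A smaller minimum width is another, since 55.2% of them were narrower than the narrowest replicate region. Scores rose with width in that list (Spearman rho 0.790), and the median width was 1245 bp for these regions against 4518 bp for the list. Narrowness alone can therefore give a low percentile, and the percentile cannot tell the 2 candidates apart. A low score cannot account for the 8 among the 10 highest-scoring regions of the list, the first of them on 2L from 4182738 to 4183738 (1001 bp), but 7 of those 8 were narrower than the narrowest replicate region, the exception being on 2R from 10079212 to 10081766 (2555 bp). All 5330 starts in the list were even numbers, against 2706 of 5484 in replicate 1 and 2574 of 5107 in replicate 2. The list therefore differed from the replicate lists in more than its minimum width. How it was made is not given in the sources used here, so neither a more permissive threshold nor a smaller minimum width was tested on the reads. No biological explanation was tested.

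Regions on X had a higher median score than regions of the autosomal arms other than 4 in each of 5 width classes, by 0.0495 to 0.115 in replicate 1, with the largest difference in the second narrowest class, and by 0.00957 to 0.0881 in replicate 2. In the narrowest 20% of regions, the median score was 0.557 on X and 0.487 on these autosomal arms in replicate 1, and 0.549 and 0.473 in replicate 2. The differences in that class were 0.0703 (95% interval from 1-Mb blocks 0.0579 to 0.0825) and 0.0761 (0.0594 to 0.0905), while in the widest 20% they were 0.0495 (0.0226 to 0.103) and 0.0184 (-0.00814 to 0.0640), the latter interval spanning 0, and 0.00847 in the replicate set (permutation p of the difference in means, with regions taken as independent, 1e-05, 0.0092 and 0.077 in the 3 lists). A higher score needed for a call on X would raise narrow regions most, and the difference dropped towards the widest 20% by 0.0208 (-0.0345 to 0.0502) in replicate 1 and 0.0578 (0.00943 to 0.0854) in replicate 2, so with 1 interval spanning 0 it may or may not contribute. The scale of the score and the treatment of X against input are not given in the sources used here, and no biological explanation was tested.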
